A study of Culex quinquefasciatus with 4 samples.

How the data were processed

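RNA was extracted from pools of 200 whole larvae of the fourth instar, and mRNA libraries were sequenced on an Illumina HiSeq instrument as paired ends of 51 nucleotides with an average insert of 200 nucleotides, per the labels' protocols. The deposited table gave 1 FPKM value (fragments scaled to transcript length and to the mapped fragments of the library) per gene and library. The header of the table names no unit, and FPKM was taken from the Cufflinks and Cuffdiff pipeline that the series' design text names and from the values, which are decimals whose sums differ between libraries (767578 for acetone and 949776 for untreated larvae). CASAVA 1.8, Trimmomatic, TopHat, Cufflinks and Cuffdiff are named in the submitters' processing notes. Their settings, the genome build and the annotation are not given in the sources used here, nor is whether Cuffdiff scaled the libraries to each other. In the deposited table every gene reached 1 FPKM in at least 1 library (the smallest maximum was 1.00), so genes low in all libraries had been removed before deposit.

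Each table column was assigned to its sample by the treatment and time in its name. Each group held 1 library, so no test, p-value or error between groups was computed, and every count is a count of genes past a fixed ratio between 2 libraries. Ratios were computed as log2(FPKM + 1) differences, which understate the change of low genes. A gene entered a comparison at 1 FPKM or more in at least 1 of its 2 libraries, which left out 205 to 595 of the 13345 genes, and counted as higher or lower at a 2-fold ratio. These settings, the comparisons and the alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, a 4-fold threshold, scaling by the median ratio to the geometric mean of the libraries (factors 0.917 for untreated, 0.881 for acetone, 1.10 for the LC50 and 1.12 for the LC70), and rescaling to one total after the 50 genes with the highest mean were left out. A restriction to genes above 0 in all libraries and outside the identifier numbers from 20000 to 39803 was added after the data were seen.

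The rule for named genes took, per comparison and direction, the 2 identifiers with the largest log2(FPKM + 1) ratio among genes above 0 in both libraries and at 10 FPKM or more in either. Of the 13345 identifiers, 0 matched the reference table (18458 rows, assembly VPISU_Cqui), so no gene is named and no coordinates are printed. For the same reason the 28 gene lists fixed beforehand (among them cytochrome P450s, glutathione S-transferases, esterases, cuticle proteins, heat shock proteins, proteases, immunity, muscle and eye genes) could not be matched to any gene, and none of them has a result.

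Library depth was not given. The ratio of the value of 1 fragment between libraries was read from the mode of the log2 ratio of 2805 untreated and LC70 genes under 3 FPKM, and likewise for the other pairs. This assumes that many of these genes had equal numbers of fragments in both libraries, which was not tested. The density at the mode was 3.21 to 8.44 times the median density. The mode was sought only in a narrow range around equal values, so a larger difference could not have been found. Absolute counts were not recovered, because transcript lengths are not in the table, so no counting interval is given, and a value of 0 is reported as listed at 0. The relation between ratios that share the acetone library was compared with 100 simulated sets of unchanged libraries with log-normal noise. The noise at each level was taken from the median absolute deviation of the ratio between the permethrin libraries. That measure gives little weight to the genes that differed most, so the noise was smaller than the full spread of those libraries. It includes any effect of dose. The counting of genes was tested on simulated data with the same noise for the LC50 against acetone, with 200 of 12946 genes changed. Of these the counting recovered 92.5% at 4-fold and 96.5% at 8-fold, and 25.0% at 2-fold. Recovery under noise of the full spread was not simulated. A 2-fold change is the threshold itself, and the pseudocount of 1 takes its ratio below that threshold before any noise. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.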

Results

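Transcript levels were measured by RNA sequencing in whole larvae of the southern house mosquito, Culex quinquefasciatus, collected in the fourth larval instar, the last one before pupation. Permethrin is a pyrethroid insecticide that acts on the voltage-gated sodium channels of insect nerves. The LC50 and LC70 are the concentrations that kill 50% and 70% of the larvae. Larvae were collected untreated at 0 h, or after 24 h in acetone, in permethrin at the LC50 or in permethrin at the LC70. Each of the 4 groups was 1 library made from a pool of 200 larvae, so no value below has a replicate error, no test between groups could be run, and each difference is one between 2 libraries. The deposited values were FPKM for 13345 genes, known only by identifiers that neither the files nor the reference table used here pair with a gene name. Therefore genes are described as groups by direction, level and identifier number, and at most 2 identifiers are given per direction in each comparison. Genome positions were not used here.

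The total number of reads per library was not given. The FPKM of 1 fragment depends on the length of the gene, but its ratio between 2 libraries was taken as the same for all genes. That ratio was estimated as the most frequent ratio among low genes. The estimate assumes that many low genes had equal numbers of fragments in both libraries, which was not tested. Within the narrow range of ratios searched, the value of 1 fragment was 1.01 times as high in the untreated library as in acetone. The untreated value was 1.05 times that at the LC50 and 1.07 times that at the LC70. On these values, the totals to which the libraries were scaled differed little. The same gene had the highest value in all 4 libraries. It took 4.47% of the summed FPKM in untreated larvae, 4.06% in acetone, 2.18% at the LC50 and 2.26% at the LC70. The 50 highest genes of each library together took 35.5%, 33.8%, 29.1% and 27.5% of the sum in the same order. The median gene stood at 6.62 FPKM in untreated larvae, 6.46 in acetone, 8.25 at the LC50 and 8.41 at the LC70. Across genes, Spearman's rho was highest for the permethrin libraries (0.961) and lowest for the untreated and LC50 libraries (0.926). Pearson's r on the log2(FPKM + 1) scale was 0.940 for the permethrin libraries and 0.942 for acetone with the LC70. Genes are not independent replicates, so these coefficients describe the libraries only.

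The comparison of acetone at 24 h with untreated larvae at 0 h gives the background of time and solvent against which permethrin is read. In it, 329 genes were at least 2-fold higher and 446 at least 2-fold lower in acetone, of 12750 genes at 1 FPKM or more in either library. The genes that were lower were weighted to abundant transcripts. Among genes with a mean of 50 to 200 FPKM, 36 were higher and 80 lower, and from 200 to 1000 FPKM 29 were higher and 52 lower. Among genes with a mean of 2 to 5 FPKM the order was the other way, with 85 higher and 69 lower. CPIJ006046 had the largest ratio of the named genes that were higher, at 27.5 FPKM in acetone and 0.369 FPKM in untreated larvae (log2 ratio 4.38 on the FPKM + 1 scale). CPIJ001874 followed at 28.4 against 0.901 FPKM (log2 ratio 3.95). Among genes above 0 in both libraries, the limit for all named genes, CPIJ028338 had the largest ratio in the other direction, at 8.00 against 1723 FPKM (log2 ratio -7.58), and its number lies in a range in which 38.9% of genes were listed at 0 in some library; CPIJ013538 followed it at 0.817 against 32.4 FPKM (log2 ratio -4.20). The balance of higher and lower genes depended on the scaling. It was 375 against 407 after each library was scaled by its median ratio, and 576 against 255 after the 50 highest genes were left out and the rest brought to one total.

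The comparison of the LC50 with acetone at 24 h addresses which transcripts differ during exposure to permethrin at equal time. In it, 620 genes were at least 2-fold higher and 173 at least 2-fold lower at the LC50, of 13030 genes compared. The LC50 and LC70 kill 50% and 70% of the larvae. At either dose a response to permethrin therefore cannot be told apart here from which larvae survived or were dying at collection. The 2-fold differences at the LC50 ran over the whole range of levels. From 10 to 50 FPKM 191 genes were higher and 38 lower, and above 1000 FPKM 17 were higher and 12 lower. CPIJ019329 stood at 119 FPKM at the LC50 and 2.60 FPKM in acetone (log2 ratio 5.06), against 14.6 FPKM in untreated larvae. CPIJ028338 had a larger ratio, at 1325 against 8.00 FPKM (log2 ratio 7.20), but was at 1723 FPKM in untreated larvae and 11.7 FPKM at the LC70. The largest ratios in the other direction belonged to CPIJ021812, at 3.33 FPKM at the LC50 against 1482 in acetone (log2 ratio -8.42), and CPIJ024478, at 3.28 against 1083 FPKM (log2 ratio -7.99). The value of CPIJ021812 in acetone was shared exactly by 6 genes. It was listed at 0 in untreated larvae and at the LC70, and CPIJ024478 was at 973 FPKM at the LC70. These last 3 identifiers have numbers from 20000 to 39803, a range in which 38.9% of the 247 genes were listed at 0 in some library, against 1.20% of the 12178 genes with lower numbers.

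The median gene itself was higher by 0.27 on the log2 scale at the LC50 than in acetone, and by 0.30 at the LC70. Relative to that shift, that is after median-ratio scaling, 316 genes were higher and 267 lower at the LC50, and 275 were higher and 276 lower at the LC70. After the 50 highest genes were left out and the rest brought to one total, the counts were 314 and 271 at the LC50, and 451 and 213 at the LC70. The excess of higher over lower genes thus depended on the scaling. Without a pseudocount, the median ratio at the LC50 was 0.33 for genes from 10 to 50 FPKM and 0.23 for genes above 1000 FPKM. At the LC70 the same levels gave 0.38 and 0.0019.

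**Figure D1:**
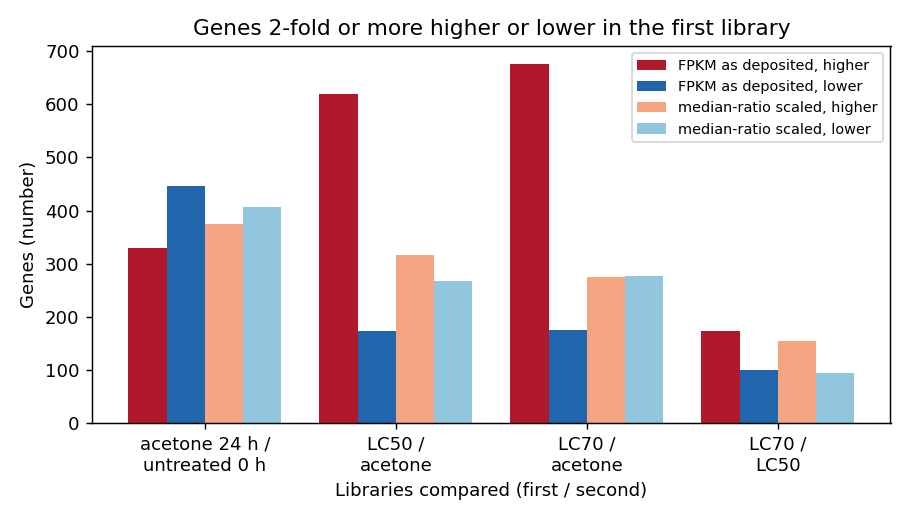
Number of genes at least 2-fold higher (red) or lower (blue) in the first of 2 libraries, for the FPKM as deposited (dark bars) and after median-ratio scaling (light bars); each group is 1 library, so there are no error bars. Permethrin against acetone gives 620 higher and 173 lower genes at the LC50 as deposited, and 316 and 267 after scaling, while the permethrin libraries differ least from each other.

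Against acetone, the LC70 library had 676 genes at least 2-fold higher and 175 at least 2-fold lower, of 13009 compared. From 10 to 50 FPKM 242 were higher and 39 lower, and above 1000 FPKM 10 were higher and 17 lower. CPIJ019329 had the largest ratio of the named genes, at 138 FPKM against 2.60 in acetone (log2 ratio 5.27). CPIJ800210 stood at 124 FPKM against 6.28 in acetone (log2 ratio 4.11) and at 118 FPKM at the LC50. In the other direction, CPIJ801597 stood at 16.4 FPKM against 410.1 in acetone (log2 ratio -4.56), with 17.5 FPKM at the LC50 and 387 FPKM in untreated larvae. CPIJ801475 stood at 0.601 FPKM against 20.2 in acetone (log2 ratio -3.73), with 0.989 FPKM at the LC50 and 30.5 FPKM in untreated larvae.

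Both doses were next compared with acetone jointly. Of the 12790 genes compared at both, 321 were at least 2-fold higher than acetone at both the LC50 and the LC70, against 27.8 for independent lists of the same sizes. A further 114 were at least 2-fold lower at both, against 2.37 for independent lists. Both comparisons share the acetone library, so part of this overlap may come from that library alone. Over the 12946 genes above 0 in all libraries and outside the number range from 20000 to 39803, the ratios at the LC50 and the LC70 correlated across genes at r = 0.76. Simulated libraries with no change but a shared control gave r = 0.50, a value that follows from giving each library the same noise. The covariance was 0.153 observed and 0.0240 simulated. The simulated noise was smaller than the full spread between the permethrin libraries, which makes the simulated covariance a low one. A noisier or unusual acetone library alone would also raise r and the covariance. The simulation therefore cannot separate that from a shared response to permethrin. Over all genes r was 0.52. With no shared control, r over the 12946 genes was 0.40 for the LC50 against acetone with the LC70 against untreated larvae, and 0.43 for the converse pairing. Spearman's rho for the same pairings was 0.23 and 0.19, against 0.70 with the shared control, and r over all genes was 0.14 and 0.15.

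**Figure D2:**
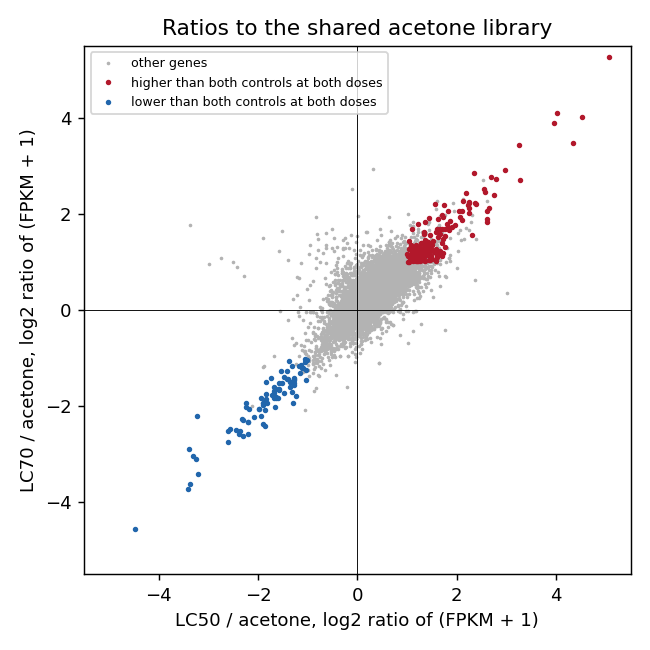
Log2 ratio of FPKM + 1 to acetone at the LC50 (x axis) and at the LC70 (y axis), with 1 point per gene for the 12946 genes above 0 in all libraries and outside the number range from 20000 to 39803; colours mark genes at least 2-fold higher (red) or lower (blue) at both doses than in both controls. The cloud follows the diagonal (r = 0.76, against 0.50 for simulated unchanged libraries of equal noise that share a control). A noisier acetone library alone would also raise r.

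Genes that stood apart from both controls at both doses were taken next. Since each group was 1 pool, a difference between pools other than permethrin could also place a gene in this set. At least 2-fold higher at the LC50 and the LC70 than in acetone and in untreated larvae were 163 genes, and 86 genes were at least 2-fold lower. The higher genes were of moderate level in the controls, with a median of 11.7 FPKM in untreated larvae and 12.6 in acetone, and reached a median of 46.2 FPKM at the LC50 and 41.5 at the LC70. As a group they took 1.08% of the summed FPKM in untreated larvae, 1.85% in acetone, 5.19% at the LC50 and 5.22% at the LC70. The lower genes were abundant in the controls, with medians of 179 FPKM in untreated larvae and 106 in acetone, against 27.3 FPKM at the LC50 and 27.7 at the LC70. They took 8.83% of the summed FPKM in untreated larvae, 7.27% in acetone, 1.81% at the LC50 and 1.91% at the LC70. The direction of these medians and shares follows from how both sets were chosen. Of the 86 genes, 20 were at 1000 FPKM or more in untreated larvae and 5 at the LC50. CPIJ019329 and CPIJ800210 belonged to the higher set, and CPIJ801597 and CPIJ801475 to the lower set. Leaving out genes at 0 in any library and the number range from 20000 to 39803 left 155 higher and 82 lower genes. Median-ratio scaling turned the balance, with 67 higher and 131 lower genes.

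**Figure D3:**
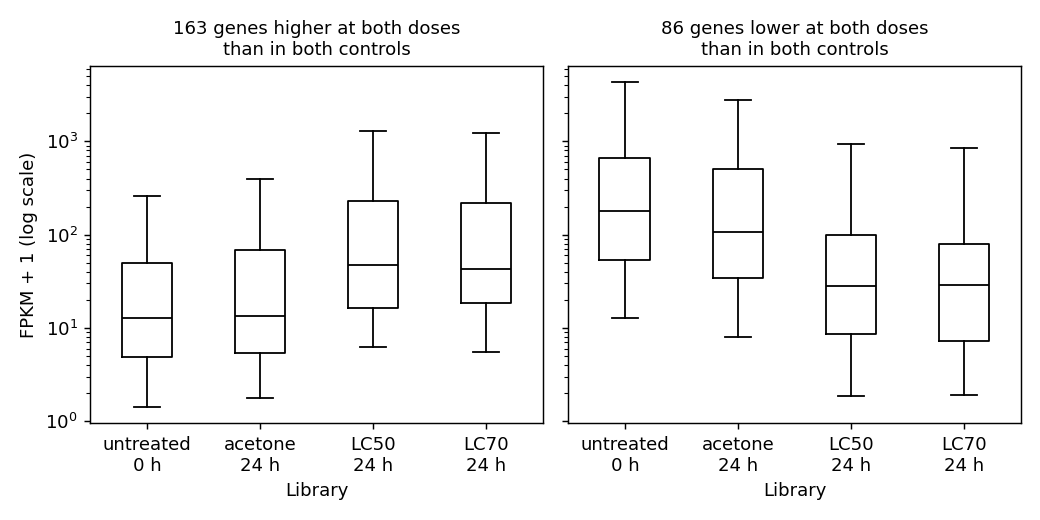
FPKM + 1 on a log axis in each of the 4 libraries for the 163 genes higher (left) and the 86 genes lower (right) at both doses than in both controls; the line is the median over genes, the box spans the quartiles and the whiskers run from the 5th to the 95th percentile of genes. The median of the lower set goes from 179 FPKM in untreated larvae and 106 in acetone to 27.3 and 27.7 at the doses.

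The comparison of the LC70 with the LC50 asks for differences by dose. In it, 173 genes were at least 2-fold higher and 100 at least 2-fold lower at the LC70, or 2.08% of the 13140 genes compared, against 6.09% for the LC50 and 6.54% for the LC70 against acetone. The size of that contrast depended on the scaling. Median-ratio scaling gave 154 higher and 95 lower genes here, against 316 and 267 for the LC50 and 275 and 276 for the LC70 against acetone. Of the 100 lower genes, 46 had numbers from 20000 to 39803. With that range and the genes at 0 in any library left out, 112 genes were higher and 29 lower. CPIJ006046, at 95.8 FPKM at the LC70 and 1.76 at the LC50 (log2 ratio 5.13), had the largest ratio outside that range, and among genes above 0 in both libraries it also had the largest ratio of acetone over untreated larvae. CPIJ024478 stood at 973 against 3.28 FPKM (log2 ratio 7.83). In the other direction CPIJ038363, also of that range, stood at 2.99 FPKM at the LC70 against 1113 at the LC50 (log2 ratio -8.13), a value that 6 genes shared exactly at the LC50, and was listed at 0 in acetone, and CPIJ028338 stood at 11.7 against 1325 FPKM (log2 ratio -6.71). Of the 267 genes higher in acetone than in untreated larvae and the 112 higher at the LC70 than at the LC50 under the same limits, 37 were shared, against 2.31 for independent lists. Those contrasts have no library in common. The 37 genes had medians of 2.11 FPKM in untreated larvae, 13.2 in acetone, 4.25 at the LC50 and 30.4 at the LC70.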

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

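With 1 library per group, the difference between the effects of the LC50 and the LC70 was not tested. Against acetone, 10 genes were at least 2-fold lower at the LC50 and at least 2-fold higher at the LC70, where independent lists of 173 and 628 genes among the 12790 compared at both doses would share 8.49. Another 5 genes were at least 2-fold higher at the LC50 and lower at the LC70, where independent lists of 566 and 175 genes would share 7.74, and all 5 were listed at 0 at the LC70. The shared acetone library makes opposite calls rarer than in independent lists even with no effect. Of the 10 genes, 7 were above 0 in all libraries and outside the number range from 20000 to 39803. By selection all 10 were lower at the LC50 and higher at the LC70 than in acetone. In 7 of them acetone was also above untreated larvae, which alone places acetone and the LC70 above both other libraries.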

How the results depend on the processing

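Counts are given here as higher and lower genes, in the order acetone against untreated (329 and 446 in the report), LC50 against acetone (620 and 173), LC70 against acetone (676 and 175), LC70 against LC50 (173 and 100), and both doses beyond both controls (163 and 86). Only values that moved by over 1.5 times are printed; the cause was not tested, except that stricter thresholds and filters admit fewer genes by construction. A 4-fold threshold gave 43 and 89, 92 and 51, 66 and 59, 45 and 53, and 15 and 26. A pseudocount of 5 gave 105 and 237, 305 and 103, 314 and 115, 69 and 47, and 97 higher. A pseudocount of 0.1 gave 616 higher, 1007 higher, 1134 higher, 274 and 189, and 264 higher. A filter at 5 FPKM gave 204 higher in acetone, and 105 and 58 for the LC70 against the LC50. Median-ratio scaling gave 316 and 267, 275 and 276, and 67 and 131 for the LC50, the LC70 and both doses, and rescaling without the 50 highest genes gave 576 and 255 in acetone, 314 and 271 at the LC50, and 102 higher at both doses. Genes above 0 in all libraries and outside the number range from 20000 to 39803, a restriction chosen after seeing the data, gave 112 and 29 for the LC70 against the LC50. Leaving out the filter changed no count, because no gene under 1 FPKM in both libraries can reach a 2-fold ratio with a pseudocount of 1. The correlation of the LC50 and LC70 ratios over all genes (0.52) was 0.50 and 0.54 with pseudocounts of 0.1 and 5, 0.54 with median-ratio scaling and 0.76 under the restriction, and without a shared control it was 0.14 and 0.15 over all genes. The ratios of the named genes kept their direction under each pseudocount and scaling. The medians of the gene lists were not run, because no identifier could be named. No replicate could be left out and no paired analysis was possible because each group is 1 library. Depth limits the table at low levels, where the number of fragments behind a value is unknown.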

Other observations

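The genes lower under permethrin were mostly lower in acetone at 24 h than in untreated larvae at 0 h as well. Of the 82 genes lower at both doses than in both controls (above 0 in all libraries and outside the number range from 20000 to 39803), 74 were lower in acetone than in untreated larvae, with a median log2 ratio of -0.62. Among all such genes 54.5% were lower in acetone than in untreated larvae. After median-ratio scaling it was 110 of 125 lower genes, with a median of -0.53, against 48.8% of all such genes. Of the 155 higher genes, 95 were higher in acetone than in untreated larvae, but 33 of 61 after median-ratio scaling. These sets were selected on both controls, and acetone was nearer to the LC50 library than untreated larvae were (SD of the log2 ratio across genes 0.445 against 0.591). An intermediate level in acetone may therefore follow in part from the selection, which was not simulated. Of the 370 genes at least 2-fold lower in acetone than in untreated larvae, 70 were at least 2-fold higher and 16 lower at the LC50 than in acetone, and 85 higher and 20 lower at the LC70. Their median log2 ratio over acetone was 0.41 at the LC50 and 0.49 at the LC70, against 0.27 and 0.29 for all such genes. Over all 12946 such genes, 537 were higher and 127 lower at the LC50, and 606 and 127 at the LC70. The shared acetone library favours higher values in the 370 genes, so their counts do not bear on whether the differences between the controls continued under permethrin. For the 267 genes at least 2-fold higher in acetone than in untreated larvae, it favours lower values. Of them 29 were at least 2-fold higher and 21 lower at the LC50, and 54 and 5 at the LC70. Their median log2 ratios over acetone, 0.011 at the LC50 and 0.15 at the LC70, lay below those of all such genes. That is the direction the shared library favours, so these medians do not bear on that question either.

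Genes with consecutive identifier numbers were often in the same set. Among the 70 lower genes with numbers up to 19998, 25 pairs had consecutive numbers, against a mean of 0.481 and a highest of 4 in 1000 shuffles within deciles of level. In all, 41 of the 70 genes were in such a pair, and the longest run held 5 genes. The 129 higher genes gave 16 pairs, against a highest of 7 in the shuffles. Pairs whose numbers lay 20 apart were 0 for the lower and 2 for the higher genes. Genes lower in acetone than in untreated larvae gave 30 pairs (highest shuffle 17). Positions on the chromosomes and sequence similarity between these genes were not analysed here.

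Of the tests of explanations that follow, the rescaling of the median gene and the correlation across genes for the third pattern were planned before their results were seen, though the restriction of genes they use was chosen after the data were seen; the others were chosen afterwards. The first pattern is that the largest ratios of the table run from 0 to high values: 70 genes were listed at 0 in some library and at 100 FPKM or more in another, and 67 of them had numbers from 20000 to 39803. A candidate explanation is 1 or a few fragments on a very short gene model, for which a single fragment gives a high FPKM, and in 68 of the genes 51.1% of the values at 100 FPKM or more equalled another gene's value in the same library exactly, against 0.469% of the values of other genes. Of the 70 genes, 51 were above 0 in 1 library only; in 17 of the other 19 the values above 0 lay within 3.13-fold. For CPIJ021812 and CPIJ038363 the explanation stays open, since their 3 high values also equalled those of other genes. But their values above 0 differed by at least 414-fold, while the value of 1 fragment was estimated to differ by at most 1.07-fold between libraries. Gene lengths were not used here, and whether some of these genes also changed biologically was not tested.

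The second pattern is the higher median gene at both doses than in acetone, on which the size of the excess of higher genes depends. A higher value of 1 fragment in the permethrin libraries is argued against only if the most frequent ratio among low genes gives that value, which was not tested. Estimated so, the value differed by -0.0485 (log2) at the LC50 and by -0.0725 at the LC70 from that in acetone, the opposite direction. The mode behind these values was sharper for the LC50 (8.44 times the median density) than for the LC70 (3.95). A fall of the most abundant genes within a fixed total could not be decided. With the 50 highest genes left out and the rest rescaled, the shift was 0.05 at the LC50 and 0.13 at the LC70, from 0.27 and 0.29. That rescaling removes a general rise whatever its cause, so the smaller shifts do not favour this explanation. The summed FPKM of the other genes was itself higher than in acetone, by 0.26 (log2) at the LC50 and 0.19 at the LC70. The sum of all genes was not fixed either, at 767578 in acetone, 890902 at the LC50 and 776639 at the LC70. Of the 20 genes with the highest mean, 9 were below acetone at the LC50 and 13 at the LC70, and 2 and 4 were at least 2-fold lower, or 6 and 6 after median-ratio scaling. FPKM sums are not sums of reads, which keeps this open, as does a true rise of most transcripts per larva, since the values are relative.

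The third pattern is the group of 37 genes at least 2-fold higher in acetone than in untreated larvae and at the LC70 than at the LC50, of which 33 were higher in acetone and at the LC70 than in both other libraries. The group was defined with genes at 0 in any library and the number range from 20000 to 39803 left out, and shuffles within deciles of level gave at most 8 such genes. The planned correlation of the contrasts over the same 12946 genes gave rho = -0.0509, the outcome set beforehand for the genes left out being the cause. Over all genes rho was -0.0495, so leaving those genes out changed it little. Over so many genes rho decides nothing about a group of this size. The 37 genes include none of the genes left out, so those genes cannot account for the group. Greater variability of some genes may contribute, since every direction exceeded independent lists: 37 against 2.31 for higher in both, 4 against 0.83 for lower in both, 2 against 0.60 for higher then lower and 6 against 3.20 for lower then higher. A difference between the pools, such as their exact age within the instar, or in library handling was not tested, since the labels give neither, and stays open.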
